A study of Rattus norvegicus with 6 samples.

How the data were processed

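Total RNA from the renal cortex of 6 male Sprague-Dawley rats, bought at 5 weeks of age, was labelled with Cy3 from 0.2 ug of RNA and hybridised to 1-colour Agilent rat arrays, per the labels' protocols. The labels put 3 rats in the vehicle group (corn oil) and 3 in the TCEP group, and the series' design text calls them biological replicates. Replicate numbers come from the sample titles, and no label says that a number marks a shared litter, cage or day.

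Per the file headers, the authors' scanner files were made with Agilent Feature Extraction 10.7.1.1 (the submitters' processing notes give 10.7), and the deposited processed signal is an intensity on a linear scale, background-subtracted and detrended by that software and not scaled between arrays. The same files hold the median intensity of each spot and of its local background, per the file headers, and per-spot flags, deposited as other values of 0 or 1, for saturation, outliers and being well above background. The deposited series matrix holds the same processed signal divided by a constant per array, on a linear scale. Checked against the scanner files for values above 1, this ratio spread by under 0.01% within an array, and the constant lay within 0.15% of the array's own 75th percentile. The column medians were between 0.104 and 0.107, and no centring of genes was seen. The array design is annotated on an older rat genome build, per the file headers, and no coordinates are given.

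The arrays hold 62976 spots, of which 1319 are controls. The 61657 non-control probes had 41457 to 42733 probes well above background per array, and at most 1 was saturated. 12 probes marked as outliers on any array were left out. Probes were named through their accessions, without versions, in a RefSeq gene table of a newer assembly (GRCr8), used for names only. 27460 probes (44.5%) matched and stood for 15284 genes, 8807 of them with several probes, and 34197 probes remained unnamed. For some fixed list members, among them Mki67, no named probe was found, so they are not analysed here.

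The log2 processed signal minus each array's log2 75th percentile over non-control probes was used throughout. A gene was represented by the probe with the highest mean signal over the 6 arrays and was tested where that probe was well above background on all arrays of at least 1 group, which left 11804 genes. Where a gene was well above background on all arrays of 1 group and none of the other, a bound on the difference of group means was computed. It was set against the higher of the lowest signal well above background and the gene's own signal on each dim array, without allowance for the spread between animals. Of 6088 tested genes with several detected probes, 2388 had a probe with the opposite sign. TCEP and vehicle were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the sole term) with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Standard errors and 95% confidence intervals come from the same moderated fit, with 5.93 degrees of freedom. Tables were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

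29 gene lists (pathways relevant to a chlorinated organophosphate in the kidney, markers of the cell types of the cortex and of tissue beside it, and handling-related genes) were fixed before the data were examined, as were the main test, the alternatives and the rule for named genes. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, which tests a list by itself and not against other genes. The rule named the 10 largest rises and falls past the adjusted threshold, up to 3 genes per direction past the threshold and detected in 1 group, up to 4 tested members of each list with the smallest adjusted p, and 13 kidney readouts, of which 11 are described here (Havcr1, Lcn2, Spp1, Clu, Cdkn1a, Nqo1, Slc22a6, Slc34a1, Lrp2, Umod and Cd68). Since 0 genes passed the threshold, the first parts of the rule named none. The rule gave 126 distinct genes, and a selection of these, up to 4 per list and fewer for lists that were not called, is described. That selection was made after their values were seen.

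Slide and scan time were read from the scanner files. Each held 1 group, so neither could be a term in the fit. No pair of arrays held identical values. Alternatives were quantile normalization, no scaling, centring on the spike-in probes, no filter on dim probes, detection on all 6 arrays, the mean over a gene's probes, each probe on its own, the authors' series matrix values, the replicate number as a block, a variance trend with robust estimation, array weights, and leaving out each array. The planned normexp correction needs mean spot signals, which are not used here, and was run with an offset of 50 on the median spot signals instead, a choice made after seeing the data. The gene and list tests were tested on simulated data with 11804 genes drawn at the measured means and at the moderated spread of the fit. The errors were drawn as normal and independent between genes. In 1 draw with 200 genes changed, 33.5% were recovered at 1.5-fold, 86.5% at 2-fold and 95.5% at 4-fold, with 4, 11 and 12 false calls. Over 20 further draws the 2-fold share ranged from 78.0% to 90.5% (mean 83.4%). With 20 changed genes, 60.5% were recovered at 2-fold, as a mean of 20 draws. With no change simulated, limma called 0 genes and camera at the preset correlation called 0 of 29 lists in the first draw and at least 1 list in 1 of the 20 further draws. The G2/M and mitosis list, shifted by 0.5, was called in 20 of 20 draws at the preset correlation and in 17 of 20 with an estimated correlation. Errors independent between genes suit the preset correlation, whereas on the arrays this list's estimated correlation was 0.69. These draws therefore do not show how the list tests behave on correlated genes.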

Results

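RNA of the renal cortex, the outer part of the kidney that holds the glomeruli and the proximal and distal tubules, was profiled on 6 single-colour Agilent arrays. Each array carried 1 male Sprague-Dawley rat, an outbred laboratory stock. 3 rats had received corn oil, the vehicle, for 4 weeks and 3 had received tris(2-chloroethyl)phosphate (TCEP), an organophosphate used as a flame retardant, at 400 mg/kg/day over the same 4 weeks. The comparison asks which transcripts of the renal cortex differ after TCEP. Between 67.2% and 69.3% of the 61657 non-control probes were well above background on an array, and the 75th percentile of the processed signal lay between 966 and 1078 intensity units. The median SD of a gene within groups was 0.13. All vehicle arrays lay on slide 1 and all TCEP arrays on slide 2, and each slide had a scan time of its own. Batch and group therefore cannot be told apart in any comparison given here. Levels are log2 signals relative to the 75th percentile of the array, differences are TCEP minus vehicle on the log2 scale, and each ± is an SD over the 3 arrays of a group.

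The 6 cortices had closely similar profiles, with Pearson correlations across genes between 0.987 and 0.995. The mean correlation was 0.992 within groups and also 0.992 between groups. The first principal component, with 38.6% of the variance, did not separate the groups. It placed TCEP replicate 1 (28.9) and vehicle replicate 2 (11.9) at one end and vehicle replicate 3 (-22.1) and vehicle replicate 1 (-11.7) at the other. On the second component, with 18.0% of the variance, the 3 vehicle arrays lay between -20.9 and -3.48 and the 3 TCEP arrays between 6.09 and 13.3.

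The 4 transcripts with the smallest unadjusted p were Gp2 and Tmem125, higher in TCEP-treated rats, and Camk1d and Xkr6, lower in them. These 4 genes were chosen after their values were seen, and none passed the adjusted threshold. Gp2, a membrane glycoprotein related to uromodulin, was at -0.80 ± 0.31 in vehicle and 1.06 ± 0.26 in TCEP arrays, a difference of 1.87 (SE 0.20, adjusted p = 0.283). Tmem125, which encodes a transmembrane protein, differed by 1.27 (SE 0.11, adjusted p = 0.181). The calcium/calmodulin-dependent kinase gene Camk1d was at 0.50 of its vehicle level (SE of the log2 difference 0.08, adjusted p = 0.181) and Xkr6, of the XK family of membrane proteins, differed by -0.69 (SE 0.07, adjusted p = 0.283). For each of these 4 genes all TCEP arrays lay on the same side of all vehicle arrays. Camk1d and Xkr6 are dim, and their log2 differences were -0.18 and -0.32 under another background correction, normexp on the median spot signals. Of 11804 genes tested with limma, 0 passed a Benjamini-Hochberg adjusted p of 0.05, and so 0 were changed at least 2-fold at that threshold. At an unadjusted p under 0.05 there were 983 genes (8.33%), of which 497 were higher and 486 lower, and 37 of the 983 differed at least 2-fold. The higher share of 50.6% became 69.6% without scaling between arrays and 62.2% with spike-in centring. For 15.6% of the genes the TCEP and vehicle arrays did not overlap, against 10% by chance for 3 against 3. A grouping that mixes them, vehicle replicates 1 and 3 with TCEP replicate 3 against the rest, gave 13.7% and 986 genes at an unadjusted p under 0.05, against 983. Testing each of the 41040 detected probes on its own, named or not, also gave 0 past the threshold and 3416 at an unadjusted p under 0.05. In data simulated at the moderated spread of the fit, 200 of the 11804 genes, drawn at random, were changed. Over 20 random draws 78.0% to 90.5% of 2-fold changes and 23.5% to 48.0% of 1.5-fold changes were recovered.

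**Figure D1:**
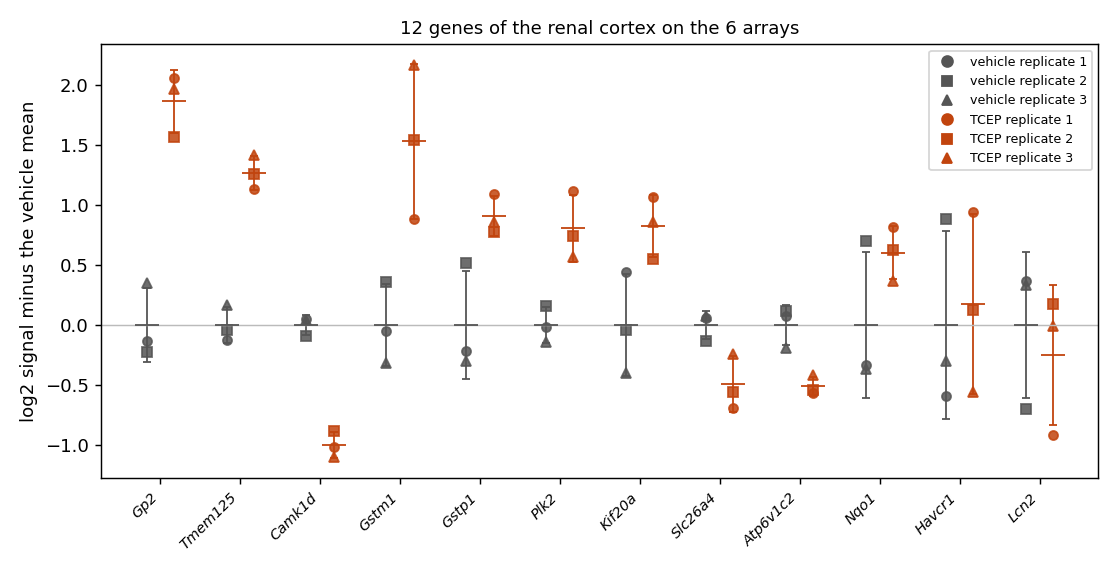
Log2 signal of 12 genes on the 6 arrays (vertical axis, relative to the vehicle mean of each gene), with grey symbols for vehicle and orange for TCEP, a symbol shape per replicate number, a bar at the group mean and error bars of 1 SD. Groups do not overlap for Gp2, Tmem125, Camk1d, Gstm1, Gstp1, Plk2, Kif20a, Slc26a4 and Atp6v1c2, which were chosen by their small p in these data. Havcr1 and Lcn2 vary as much within groups as between them. None of the 12 passed the adjusted threshold.

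Most measured genes of cell division had higher means in TCEP-treated cortex, but their lists were called at the preset correlation alone. Of 24 measured members of the G2/M and mitosis list, 23 were higher and 1 was lower, with a median difference of 0.56 (0.31 with array weights and 0.33 with normexp). Kif20a, a kinesin needed for cytokinesis, differed by 0.83 (SE 0.24), Ube2c, a ubiquitin-conjugating enzyme that drives mitotic exit, by 0.66 (SE 0.22), Cenpf, a kinetochore protein, by 0.63 (SE 0.20) and Prc1, a component of the central spindle, by 0.58 (SE 0.18). Of 26 members of the DNA replication and S phase list 21 were higher, with a median of 0.16 (0.08 without vehicle replicate 3 and 0.24 without TCEP replicate 3). They included Rrm2, a subunit of ribonucleotide reductase, at 1.08 (SE 0.30) and Cdc45, part of the replicative helicase, at 0.48 (SE 0.12). With limma's camera at a preset inter-gene correlation of 0.01 the adjusted p was 2.11e-09 for the G2/M and mitosis list and 0.00142 for the DNA replication and S phase list. The correlation estimated from the arrays was 0.69 for the G2/M and mitosis list and 0.19 for the DNA replication and S phase list. Both lie above the preset 0.01, which treats the members as nearly independent. Both lists had an adjusted p = 0.582 with camera at an estimated correlation and 0.448 with fry. For the G2/M and mitosis list 2 groupings that mix vehicle and TCEP arrays gave smaller values at the preset correlation, 1.04e-19 for vehicle replicate 1 with TCEP replicates 1 and 3 against the rest and 9.37e-12 for vehicle replicate 1 with TCEP replicates 1 and 2. No member passed the threshold over all genes, and 0 in either list passed when adjusted over the list alone, where the smallest values were 0.0775 and 0.108. The mean of the G2/M and mitosis list lay at 0.39, 0.10 and 0.21 on the TCEP arrays and at 0.14, -0.34 and -0.50 on the vehicle arrays, relative to each gene's mean, so that vehicle replicate 1 lay within the TCEP range.

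Targets of p53, the transcription factor of the DNA damage response, were also higher, at 19 of 24 members with a median of 0.11. Plk2 and Plk3, which encode polo-like kinases induced by stress, differed by 0.81 (SE 0.16) and 0.41 (SE 0.10), and Mgmt, which encodes a DNA alkyl transferase, by 0.39 (SE 0.09). These 3 genes passed when adjusted over the list alone (each at 0.0483), and 0 members did over all genes tested. Cyclin D1 (Ccnd1) differed by 0.49 (SE 0.15). Cdkn1a, the cell cycle inhibitor most often used as a p53 readout, was level, at 4.85 ± 0.03 and 4.86 ± 0.10, a difference of 0.01 (95% confidence interval -0.17 to 0.19). A further probe of Plk3 gave -0.30, and the mean over its probes was 0.05. The list had an adjusted p of 0.0111 with camera at the preset correlation and an adjusted p = 0.469 with an estimated correlation. That estimate was -0.013, below the preset 0.01, so correlation between members does not account for the lost call. Without TCEP replicate 1 the median was 0.07 and the preset adjusted p 0.0671, and without TCEP replicate 3 the median was 0.20.

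Glutathione S-transferases, which conjugate electrophiles to glutathione, were higher in 20 of 21 members, with a median of 0.18 (0.11 without vehicle replicate 3). Gstm1 differed by 1.53 (SE 0.35), Gstp1 by 0.91 (SE 0.23), Gsta5 by 0.46 (SE 0.11) and Gstt1 by 0.39 (SE 0.09), each with all TCEP arrays above all vehicle arrays. The 1 lower member, the dim microsomal Mgst2, chosen after its values were seen, differed by -0.95 (SE 0.37, unadjusted p = 0.0455), and by -0.44 with normexp. The 4 higher genes named passed when adjusted over the list alone (each at 0.0432) and 0 did over all genes. The list's adjusted p was 3.88e-05 with camera at the preset correlation, and it had an adjusted p = 0.499 with an estimated correlation of 0.15. Members of this family and of the UGT and carboxylesterase families have near-identical copies, so a probe can take up signal from a relative, and their single-gene values are uncertain to that extent.

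In the list of esterases and alcohol or aldehyde dehydrogenases 18 of 22 members were higher (median 0.09, adjusted p = 0.0111 with camera at the preset correlation, adjusted p = 0.499 with an estimated correlation of 0.03). They included the paraoxonase gene Pon3 at 0.36 (SE 0.10) and the alcohol dehydrogenase gene Adh6 at 0.92 (SE 0.33). The carboxylesterase gene Ces1c was well above background on all 3 TCEP arrays and on 0 vehicle arrays and was at least 2.85-fold higher with TCEP (adjusted p = 0.561), a bound set against the lowest signal well above background on each vehicle array. The median with Ces1c at its bound stayed at 0.09. Without TCEP replicate 3 the list's adjusted p was 0.0853. Of 21 cholesterol synthesis genes 19 were higher (median 0.10, adjusted p = 0.00787 at the preset correlation, adjusted p = 0.582 with an estimated correlation), among them Nsdhl at 0.19 (SE 0.06). That call ended without TCEP replicate 2 (median 0.03, adjusted p = 0.296) and without vehicle replicate 1 (median 0.11, adjusted p = 0.123), and the median was 0.19 with array weights and 0.16 without TCEP replicate 3. The NRF2 antioxidant list (20 of 28 higher, median 0.11, adjusted p = 0.132) was not called (called in 3 of 17 settings: spike-in centring, 0.0323, without TCEP replicate 3, 0.0493, and without vehicle replicate 2, 0.0484; median 0.05 with normexp), although Akr7a3, an aflatoxin aldehyde reductase, differed by 0.65 (SE 0.18) and sulfiredoxin (Srxn1) by 0.67 (SE 0.26), while glutathione reductase (Gsr) differed by -0.18 (SE 0.07), with all TCEP arrays below all vehicle arrays, and by 0.02 with normexp. Nqo1, the usual readout of NRF2, differed by 0.60 (SE 0.31, adjusted p = 0.661), with vehicle replicate 2 inside the TCEP range. The CAR, PXR and AhR target list, with 10 of its 25 members measured, was not called either (7 of 10 higher, median 0.27, adjusted p = 0.109; median 0.09 without TCEP replicate 1 and 0.16 with normexp), with the glucuronosyltransferase gene Ugt1a6 at 0.49 (SE 0.13). It was called in 4 of 17 settings, with no filter on dim probes (0.0130), the replicate block (0.0306), spike-in centring (0.0122) and without TCEP replicate 3 (0.0229).

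Markers of the acid-base-regulating intercalated cells were lower in TCEP-treated cortex, in 13 of 14 members with a median of -0.25. Atp6v1c2 and Atp6v1b1, subunits of the proton pump, differed by -0.51 (SE 0.10) and -0.29 (SE 0.07), and Slc26a4, the chloride-bicarbonate exchanger pendrin, by -0.49 (SE 0.13). These 3 genes passed when adjusted over the list alone (0.0379, 0.0420 and 0.0490) and 0 did over all genes. The list's adjusted p was 8.09e-06 with camera at the preset correlation, and it had an adjusted p = 0.469 with an estimated correlation of 0.08. Its mean lay between -0.20 and -0.05 on the TCEP arrays and between 0.08 and 0.16 on the vehicle arrays, without overlap. Distal convoluted and connecting tubule markers were lower in 11 of 12 members (median -0.20, adjusted p = 0.0111 at the preset correlation, adjusted p = 0.582 with an estimated correlation). The calcium channel gene Trpv5 differed by -0.42 (SE 0.12) and Calb1, which encodes the calcium-binding protein calbindin, by -0.58 (SE 0.21). That call ended without vehicle replicate 1 (median -0.06, adjusted p = 0.225), and the median was -0.32 without vehicle replicate 2. The mean of this distal list lay between -0.132 and -0.099 on the TCEP arrays and at 0.343, -0.101 and 0.100 on the vehicle arrays. Vehicle replicate 2 thus lay within the TCEP range.

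Other tubule segments were not called. Collecting duct principal cell markers were lower in 11 of 14 members (median -0.15, adjusted p = 0.0507), with the vasopressin receptor gene Avpr2 at -0.33 (SE 0.13). That list lies at the threshold and was called in 8 of the 17 settings with a preset correlation, as many as the neutrophil and erythroid list, with a median of -0.36 (adjusted p = 0.000349) without vehicle replicate 2 and -0.07 (adjusted p = 0.249) without vehicle replicate 1. Thick ascending limb markers had a median of -0.04 but a mean of 0.05 (adjusted p = 0.299). In that list the potassium channel gene Kcnj1 was at -0.32 (SE 0.09) and Umod, which encodes uromodulin, at 0.04 (SE 0.16). The list's median turned to 0.01 without scaling between arrays, and without TCEP replicate 1 it was -0.12 and the list was called (adjusted p = 0.0218). Proximal tubule transporters had a median of 0.03 (adjusted p = 0.899), and proximal tubule enzymes had a median of 0.00 with a mean of 0.05 (adjusted p = 0.968) and a median of 0.04 without scaling. Among transporters, the monocarboxylate carrier gene Slc5a8 differed by -0.54 (SE 0.10, 0.0605 adjusted over the list alone) and the water channel gene Aqp1 by 0.21 (SE 0.08). The organic anion transporter gene Slc22a6, the phosphate transporter gene Slc34a1 and the endocytic receptor gene Lrp2 differed by 0.15 (95% confidence interval -0.19 to 0.50), -0.04 (-0.25 to 0.18) and 0.04 (-0.22 to 0.31).

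**Figure D2:**
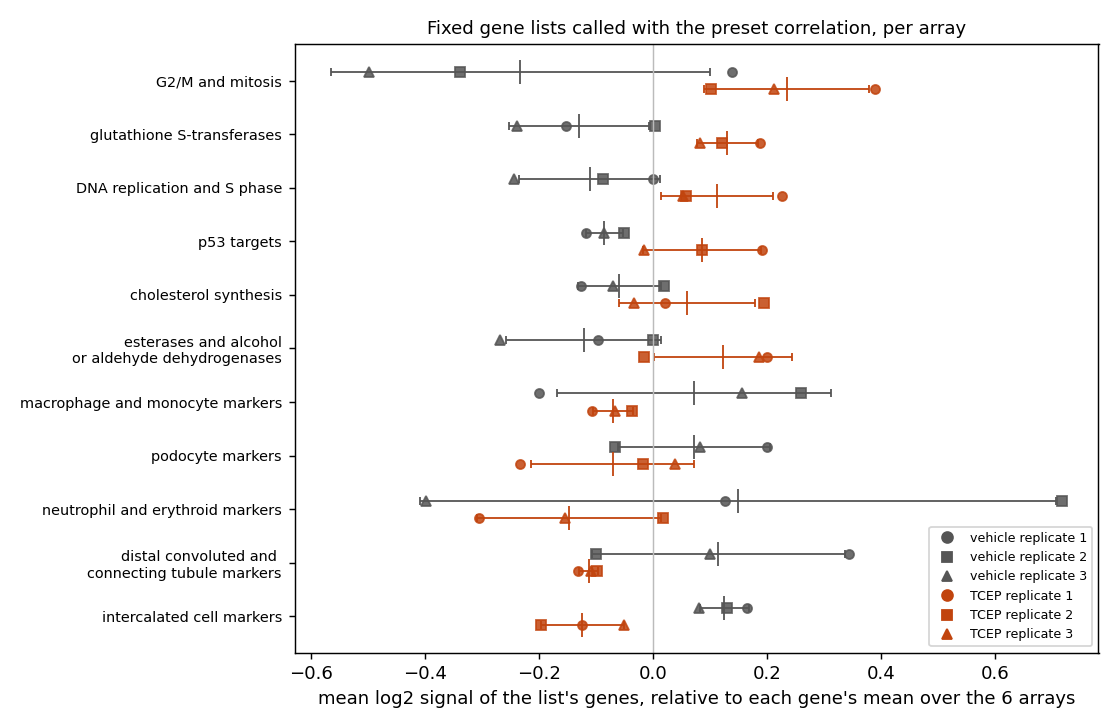
Mean log2 signal of the genes of 11 lists on each array (horizontal axis, relative to each gene's mean over the 6 arrays), with grey symbols for vehicle and orange for TCEP, a symbol shape per replicate number, a bar at the group mean and error bars of 1 SD. Groups do not overlap for the glutathione S-transferase, DNA replication and S phase, p53 target and intercalated cell lists, and vehicle replicate 2 stands apart at 0.72 for neutrophil and erythroid markers.

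Podocyte markers, of the glomerular filter, were lower in 14 of 15 members (median -0.13, adjusted p = 0.00787 at the preset correlation, adjusted p = 0.582 with an estimated correlation). Nephrin (Nphs1) differed by -0.32 (SE 0.14). The call ended without TCEP replicate 1 (median -0.06, adjusted p = 0.0996) and without vehicle replicate 1 (median -0.07, adjusted p = 0.125), and the median was -0.22 without vehicle replicate 2. Macrophage and monocyte markers were lower in 15 of 17 members (median -0.13, adjusted p = 0.0111 at the preset correlation, adjusted p = 0.582 with an estimated correlation), with the complement gene C1qb at -0.36 (SE 0.20) and Cd68 at -0.08 (SE 0.17). Without vehicle replicate 2 their median was -0.04 (adjusted p = 0.630), and without vehicle replicate 1 it was -0.23. Neutrophil and erythroid markers were lower in 10 of 11 members (median -0.19, adjusted p = 0.0479 at the preset correlation, adjusted p = 0.672 with an estimated correlation). This followed vehicle replicate 2, whose list mean was 0.72 against 0.13 and -0.40 on the other vehicle arrays. The call ended without vehicle replicate 2 (median -0.08, adjusted p = 0.741), without vehicle replicate 1 (-0.18, 0.0797), without TCEP replicate 1 (-0.19, 0.173) and without TCEP replicate 3 (-0.26, 0.0636), and the median was -0.36 without vehicle replicate 3. S100a9, an abundant neutrophil transcript, was at -0.80 ± 1.45 in vehicle and -1.81 ± 0.52 in TCEP arrays. Lymphocyte markers (median -0.08, adjusted p = 0.205) showed the same array apart, with a mean of 0.50 on vehicle replicate 2. Their median was 0.19 without that array and -0.01 with array weights. Without vehicle replicate 1 it was -0.27, and camera called the list (adjusted p = 0.00402). Endothelial markers (-0.06, adjusted p = 0.185) and mesangial, fibroblast and smooth muscle markers (-0.06, mean 0.01, adjusted p = 0.899) were not called, with Pdgfra at 0.26 (SE 0.08) in the latter. Adipose and adrenal markers, which track tissue beside the kidney, were not called (0.11, adjusted p = 0.899), with 7 members higher and 4 lower. The adipocyte gene Fabp4 differed by 1.41 (SE 0.51), whereas the list members Cfd and Cyp11b2 differed by -0.82 (SE 0.37) and -0.30 (SE 0.11).

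Transcripts that mark tubular injury were not detectably different in the main test. Havcr1, which encodes kidney injury molecule 1, differed by 0.17 (95% confidence interval -1.10 to 1.44), Lcn2 by -0.25 (-1.24 to 0.74), osteopontin (Spp1) by -0.15 (-0.67 to 0.36) and clusterin (Clu) by 0.24 (-0.91 to 1.38). These intervals leave room for 2-fold differences of Havcr1, Lcn2 and Clu. The tubular injury and repair list, with 17 of 27 members lower, had a median of -0.06 (adjusted p = 0.127), with galectin-3 (Lgals3) at -0.28 (SE 0.08). That list was called with camera under no scaling (median -0.02, adjusted p = 0.0433), and its median was -0.04 with array weights and with normexp. Lists of extracellular matrix and fibrosis (median -0.01, adjusted p = 0.713), inflammation and chemokines (-0.08, adjusted p = 0.127) and interferon, complement and antigen presentation (-0.09, adjusted p = 0.134, and -0.01 without TCEP replicate 2 and -0.04 without vehicle replicate 2) were not called. Camera called the interferon list without TCEP replicate 1 (-0.10, adjusted p = 0.0218) and without vehicle replicate 1 (-0.08, 0.0127). It called the inflammation list without vehicle replicate 3 (-0.14, 0.0132) and without TCEP replicate 3 (-0.14, 0.0493). The inflammation median was -0.02 without TCEP replicate 2 and 0.01 without vehicle replicate 2. Timp2, a matrix protease inhibitor, differed by -0.24 (SE 0.07). Fatty acid oxidation genes under PPAR alpha were lower in 20 of 30 members (median -0.07, adjusted p = 0.0649), with the peroxisomal enzyme gene Ehhadh at -0.37 (SE 0.14), and were called in 6 of 17 settings, among them quantile normalization (0.0173) and no scaling (0.0337, median -0.03). Their median was -0.02 without TCEP replicate 1, -0.04 without vehicle replicate 2 and -0.11 without TCEP replicate 3. The respiratory chain (0.03, adjusted p = 0.361, with medians from -0.01 with normexp to 0.08 with no scaling), the unfolded protein and integrated stress response (0.02, adjusted p = 0.978) and the immediate early genes (-0.08, adjusted p = 0.321, and -0.01 without TCEP replicate 3, -0.02 without vehicle replicate 1, -0.13 without TCEP replicate 1 and -0.16 without vehicle replicate 3), which track handling of the tissue, were not called, and Atf3, a member of both of the latter, was at -0.60 (SE 0.17). Over the 29 lists, camera at the preset correlation called 11, of which 6 were higher and 5 lower, whereas 0 were called with an estimated correlation and 0 by fry, whose smallest adjusted p was 0.224 for a shift of a list in 1 direction and 0.105 for changes in either direction. With normexp on the median spot signals camera called 4 lists, those of G2/M and mitosis, DNA replication and S phase, glutathione S-transferases and intercalated cells, and the calls of the other 7 ended (adjusted p from 0.0666 to 0.204). Their medians there were 0.13 for esterases and dehydrogenases, 0.09 for p53 targets, 0.09 for cholesterol synthesis, -0.20 for distal convoluted and connecting tubule, -0.12 for macrophage, -0.13 for neutrophil and erythroid and -0.07 for podocyte markers. The macrophage and monocyte call also ended with array weights (median -0.07, adjusted p = 0.213), and the neutrophil and erythroid call with array weights (0.0709), the mean over probes (0.0630), no filter on dim probes (0.0598) and quantile normalization (0.0511), with medians there from -0.21 to -0.19. List means of the TCEP and vehicle arrays did not overlap for 4 of the 29 lists, against 10% expected by chance. An exact permutation test of 3 arrays against 3 cannot give a p below 0.10.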

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

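The tests of gene counts over other splits, of a single left-out array, of immune cells and of slide or scan were chosen after the results were seen, and so were the repeats without Cldn14 and with each array left out. The simulation with 20 genes was chosen after the one with 200, and the list medians had been seen when the thick ascending limb test was written. 15 unnamed probes were well above background on all 3 TCEP arrays and on no vehicle array. These probes lie outside the gene comparison and were singled out as a signal above the control level. 38 did the opposite, and the other 18 of the 20 choices of 3 arrays gave 7 to 84 such probes.

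With limma, 0 genes passed the adjusted threshold, and 983 had an unadjusted p under 0.05. A spread between animals too large for 3 against 3 could account for this. Simulation argues against it for many 2-fold changes in genes drawn at random, since 86.5% of 200 were recovered, and 60.5% where 20 genes change. Its errors were drawn as normal and independent, at the moderated spread of the fit. It says little on genes with a wide spread, such as Havcr1 (SE 0.52). Smaller changes stay open. Leaving out 1 array gave at most 1 gene, but fewer arrays recover fewer changes, and recovery was simulated for 3 against 3 alone. A single array that hides the changes therefore stays open. Other splits of the arrays say nothing here, since with a real count of 0 all 10 give as many genes, and as many changed at least 2-fold, whatever the data (highest other 1 for both).

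The G2/M and mitosis list was higher with TCEP by a median of 0.56. More immune cells in the TCEP samples might bring dividing cells. The macrophage and lymphocyte markers had a median of -0.12 over 33 genes, with an upper 95% bootstrap bound over genes, not animals, of -0.08. The cut was 0.28, taken from the G2/M list's own median after the results were seen. Vehicle replicate 2 lowers the immune median: without it the macrophage list was at -0.04, the lymphocyte list at 0.19 and both together at -0.00 (bound 0.12, cut 0.21). A broad rise of these markers was thus not seen. The cut assumes that they rise in proportion to the G2/M list, so a small number of dividing immune cells stays open. Slide or scan cannot be told apart from TCEP, because 0 slides held both groups, and a difference in division between the animals that is due to TCEP is open for the same reason. The splits, 10 with the real one included, are too few for a share under 0.05. The real split alone shifted the list as much (real 0.56, highest other 0.51). However, 2 mixed splits gave a smaller adjusted p with camera than the real 2.11e-09 (1.04e-19 and 9.37e-12). As many lists were called by 3 of 10 splits, the real one among them (real 11, highest other 13).

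Intercalated cell markers and distal convoluted and connecting tubule markers were lower with TCEP, by medians of -0.25 and -0.20. For the latter list the mean of vehicle replicate 2 lay within the TCEP range. Less distal tubule tissue in the TCEP samples may lower thick ascending limb markers as well, but their mean was 0.05 over 12 genes against -0.24 over the 26 others (permutation p = 0.00190). Cldn14, which varied widely between animals, carries part of that gap: without it the mean was -0.06 and the permutation p 0.0123. Without TCEP replicate 1 the means were -0.11 and -0.23 (permutation p = 0.0549), and with any other array left out the permutation p lay between 0.000200 and 0.00730, so the gap is smaller without that array and less distal tissue stays open. The permutations shuffle genes between the lists, so their p does not measure the spread between animals. Collecting duct principal cell markers were not part of the test and were lower in 11 of 14 members (median -0.15, not called). The limb list was tested without Slc12a1, which had no named probe. Slide or scan cannot be told apart from TCEP here either, because 0 slides held both groups, and an effect of TCEP on these cells stays open.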

How the results depend on the processing

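Array signal was well above background for 67.2% to 69.3% of probes, and the other probes were dim. Slide could not be a block, since each slide held 1 group. Normexp could not be run on mean spot signals as planned and was run on median spot signals, chosen after seeing the data. The variance trend with robust estimation gives no list test, and testing every probe gives counts alone. Causes were not tested unless stated.

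Genes changed by TCEP, with or without the 2-fold limit, numbered 0 by limma in each other setting (384 with spike-in centring to 1568 with normexp at an unadjusted p under 0.05, 983 as reported, 995 with trend and robust, 1410 with array weights, and 3416 of 41040 when each probe was tested) and 0 to 1 when each array was left out. The 1 gene was Dio2 without TCEP replicate 3 (adjusted p = 0.0432), well above background on 2 TCEP and 0 vehicle arrays. Its mean on those TCEP arrays was at least 1.88-fold higher, a bound without allowance for spread, so its place among 2-fold changes rests on a fitted value. With all 6 arrays and no filter its adjusted p was 0.660. Gene lists changed by TCEP numbered 11, but 0 with the estimated correlation, 0 with fry and 4 with normexp (G2/M, S phase, glutathione S-transferases and intercalated cells). Those 4 were called in all 17 settings with a preset correlation. Of the lists not called, 10 were called in some of the 17: collecting duct in 8, PPAR alpha in 6, CAR, PXR and AhR in 4, NRF2 in 3, inflammation and interferon in 2 each, and endothelial, lymphocyte, thick ascending limb and tubular injury in 1 each. Leaving out each array gave 9 to 13 lists. With the replicate number as a block there were 0 genes (850 unadjusted) and 14 lists. Correlations of deviations were -0.15, -0.10 and 0.23 for equal numbers and lay between -0.33 and 0.37 for unequal ones. With 3 arrays per group they cannot tell whether the numbers pair the animals. No scaling moved the median of all genes by most, to 0.05. Of the named genes' alternatives other than left-out arrays 606 of 614 kept direction and side of the threshold, and 322 of 336 with an array left out. For lists these were 286 of 348 (34 no longer called, 16 newly called, 12 reversed) and 132 of 174.

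Directions turned for these results. With array weights: Cdkn1a -0.0182, Umod -0.0107, extracellular matrix and fibrosis 0.0240, proximal tubule enzymes 0.0291. With the mean over probes: unfolded protein and integrated stress response -0.0112. With no scaling: Slc34a1 0.00519, extracellular matrix and fibrosis 0.0298, proximal tubule enzymes 0.0397, thick ascending limb markers 0.00652. With normexp: Cd68 0.0235, Cdkn1a -0.00338, Gsr 0.0172, Lrp2 -0.0780, proximal tubule enzymes 0.0317, respiratory chain -0.00973, unfolded protein and integrated stress response -0.0131. With quantile normalization: Cdkn1a -0.0169, unfolded protein and integrated stress response -0.0103. With spike-in centring: extracellular matrix and fibrosis 0.0117, proximal tubule enzymes 0.0216.

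Leaving out each array in turn turned further directions, given as lowest to highest: Cd68 -0.19 to 0.10, Cdkn1a -0.0494 to 0.0464, Clu -0.0879 to 0.63, Havcr1 -0.21 to 0.62, Lcn2 -0.60 to 0.0832, Lrp2 -0.0223 to 0.15, Slc34a1 -0.0866 to 0.0410, Spp1 -0.27 to 0.0617, Umod -0.0879 to 0.14, adipose and adrenal markers -0.0767 to 0.24, endothelial markers -0.11 to 0.00307, extracellular matrix and fibrosis -0.10 to 0.0905, inflammation and chemokines -0.14 to 0.0110, lymphocyte markers -0.27 to 0.19, mesangial, fibroblast and smooth muscle markers -0.0883 to 0.0690, proximal tubule enzymes -0.0857 to 0.0577, proximal tubule transporters -0.00833 to 0.0955, thick ascending limb markers -0.12 to 0.0372, unfolded protein and integrated stress response -0.0384 to 0.0989.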

Other observations

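Some genes differed far more between animals than between groups. The genes named here were chosen after their values were seen. Of 11804 genes, 89 (0.754%) had an SD within groups of at least 1. Gal, which encodes the neuropeptide galanin, lay at 4.12, -5.53 and 3.99 on the vehicle arrays and at -8.72, 3.00 and 3.13 on the TCEP arrays, relative to its mean. Fam111a was 2.84, -3.69 and 2.99 on the vehicle arrays and -2.93, -2.99 and 3.78 on the TCEP arrays. Rbp4, which encodes retinol-binding protein, and Ephx2, which encodes soluble epoxide hydrolase, had SDs of 2.78 and 2.50. Rnase6 was well above background on all 3 vehicle arrays and on no TCEP array (adjusted p = 0.533). Its mean was at least 1.97-fold lower on the TCEP arrays, a bound without allowance for the spread between animals.

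A candidate explanation is inherited differences in expression between outbred rats, a hypothesis that no genotype tests here. Another candidate, a sequence variant under 1 probe, predicts that other probes of the gene do not share the spread. In 75% of such genes with another detected probe (21 of 28), that probe showed at least 50% of the spread, as for Fam111a (80.3%, r = 0.997) and Rbp4 (101%). This argues against a variant under 1 probe alone as the cause for those 21 genes. It stays open for the other 7, Crygd (10%), Myorg (14.5%), RT1-CE3 (22.5%), Sbp (23.6%), Pcdh9 (27.5%), Cldn14 (34.0%, r = 0.913) and Sspo (37.8%, r = 0.943), and for the strongly variable genes with no other detected probe, Gal and Ephx2 among them. The other probes of Cldn14 and Sspo followed the same animals at a smaller spread. Probe positions were not checked, so for the 21 genes a variant that reaches both probes stays open. Agreement between probes also cannot tell inherited differences from other differences between the animals, which were not tested.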
